A study of Homo sapiens with 4 samples.

How the data were processed

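Single-cell RNA sequencing had been done on cultures of the human embryonic stem cell line H9, differentiated in vitro towards blood-forming tissue and harvested on day 18. The cells carried reporters at the SOX17 and RUNX1C loci. Each of 4 culture conditions gave 1 Drop-seq library, a method in which single cells are captured with barcoded beads in droplets. The conditions cross vehicle (DMSO) or SB/CHIR with static culture or orbital shear. SB/CHIR is the pair of SB431542 at 4 µM, an inhibitor of the receptors for TGF-beta and activin, and CHIR99021 at 3 µM, an inhibitor of GSK3 that activates WNT signalling, both given from day 2 to day 4. Shear was applied by orbital rotation at 100 rpm from day 10 for 8 days. With 1 library per group there are no replicates, and the sources do not say whether the libraries came from separate differentiation runs.

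The authors deposited, for each library, a table of whole-number counts per gene and cell barcode, with no normalisation. Tests on the deposited values found whole numbers only, gene symbols in one dimension and barcodes in the other, and column sums that differed from barcode to barcode. The processing notes name the genome build GRCh38 and Cell Ranger 1.3.0 without giving the role of that program. Whether reads were collapsed by molecular identifier, how barcodes were called as cells, and the annotation release are not given in the sources used here, so the values are called counts and not molecules. Dissociation used TrypLE or collagenase, and which library received which enzyme is not stated. The deposited names share 1 suffix for both static libraries and another for both shear libraries, and its meaning is not given. Gene positions were taken from GENCODE release 29 on GRCh38.

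Barcodes with at least 200 genes and at most 20% mitochondrial counts were kept, which removed 108 of 7550 barcodes. Cells of all 4 libraries were clustered together with scanpy 1.11.5 and anndata 0.12.19 in Python 3.11.15. Mitochondrial, ribosomal protein, XIST and Y-linked genes were removed for the clustering. The remaining counts per cell were scaled to the median total and log-transformed with 1 added. The 2000 most variable genes were then chosen per library and combined. Principal components (30), a graph of 15 neighbours and Leiden clustering at resolution 0.8 with seed 0 followed, using the Leiden method of igraph 0.11.9. No batch integration was applied, because each library is a condition. Scrublet called 56 of 7442 cells as doublets, and these cells were kept. Clusters were named from 18 marker sets fixed before the data were examined. A name required a median fold of at least 1.5 over the set, at least 3 markers at least 2-fold up, and no lead by markers of another class. These naming thresholds were set after the clusters had been seen, so the unnamed share is given for each library.

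Counts were summed over the kept cells of each library, or over the cells of 1 class in 1 library, and divided by the sum's total and scaled to a total of 1000000 to give CPM. Each contrast is a ratio of 2 such values with an exact conditional binomial 95% interval, and each share of cells has an exact Clopper-Pearson 95% interval, both from scipy 1.17.1. These intervals and the floors cover counting error only and say nothing of variation between cultures. The ratio intervals treat each count as an independent draw and so also leave out variation between cells. They are too narrow where few cells hold most counts of a gene. A value of 0 counts was set to a floor of 3 counts in that library, and ratios against it are lower bounds. No test, p-value or standard error was computed. An additive model of drug and shear would leave 1 residual degree of freedom and was not fitted.

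Genes with at least 100 counts over the 4 libraries entered the whole-library comparisons, and genes with at least 50 counts over the 4 sums of a class entered the comparisons within it. A class entered a contrast with at least 50 cells in both libraries. Genes were counted by size, as those at least 2-fold higher or at least 2-fold lower in both contrasts of a factor. The 2 contrasts of 1 factor use separate libraries, whereas the drug and shear contrasts share libraries. Beside each count stands the number that would arise if the directions in the 2 contrasts were independent across genes.

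Another 33 gene lists were fixed before the data were examined. For each list, the median log2 ratio of members with at least 20 counts was taken, if at least 3 members qualified. Its percentile was found among 10000 random lists of the same size matched on mean expression in 20 bins. Counting intervals of list medians came from 1000 resamplings of the counts. The percentiles describe these libraries and are not tests. Members at 0 counts in 1 library of a contrast entered the median at their bound.

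Named genes followed a rule fixed before the data were examined. It took, per factor, the 10 genes highest and the 10 lowest (8 and 8 within a class) among those at least 2-fold in the same direction in both contrasts, ranked by the interval bound nearest a ratio of 1. For the combination of both factors it took the 5 largest positive and 5 largest negative differences of log2 ratios among genes with at least 200 counts. Members of the fixed lists and marker sets were also named.

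The counting step was tested on simulated data. All 50 genes simulated at 4-fold were called in each direction for each factor. At exactly 2-fold, between 16.0% and 28.0% were called, since the threshold sits at that size. Of 11442 genes in the simulated SB/CHIR comparison, 1 unchanged gene was called, and of 11438 in the shear comparison, 0 were. Without replicates, variation between cultures could not be estimated from these libraries. The simulation therefore checks the counting step only and gives no rate of false calls for the real libraries.

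Alternatives covered the cell filter, the clustering resolution, centring of genes within libraries, removal of called doublets, TMM factors from edgeR 4.0.16 in R 4.3.3, totals without haemoglobin and mitochondrial genes, per-cell weighting, the gene filter, the size threshold, and class-standardised sums. The last gave each of the 6 classes with at least 20 cells in every library its mean share over the 4 libraries. Erythroid-, granulocyte-, progenitor- and cardiomyocyte-like and unnamed cells are left out of these sums, so they say nothing of lists expressed mainly in those cells. Thinning to the smallest library, a minimum of 40 cells per class and standardising with the classes of resolution 1.6 were added after seeing the data. Leaving out replicates, paired analyses and other splits of the samples do not apply to 1 library per group.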

Results

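The data are single-cell transcript counts from cultures of H9, a human embryonic stem cell line, taken on day 18 of differentiation towards blood-forming tissue. A 2 × 2 design crossed vehicle (DMSO) or SB/CHIR with static culture or orbital shear, and each of the 4 groups holds 1 Drop-seq library. There are no replicates, so no test was made, and each interval below is a 95% interval that covers counting error only. The static DMSO library held 1761 barcodes and 4445427 counts, the static SB/CHIR library 1645 and 2594840, the shear DMSO library 1977 and 6992639, and the shear SB/CHIR library 2167 and 5184795. The study states 2100 to 3000 cells per condition. Median counts per barcode were 1750, 1145, 2662 and 1702 in the same order, and median genes per barcode were 1030, 730, 1453 and 1039.

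Composition of the counts differed between libraries. Ribosomal protein genes took 7.35% of the counts in static DMSO, 12.4% in static SB/CHIR, 6.69% in shear DMSO and 10.9% in shear SB/CHIR. The nuclear RNA MALAT1 took 5.52%, 3.41%, 5.60% and 1.83%, and mitochondrial genes took 3.26%, 4.13%, 4.22% and 3.94%. The median log2 ratio over all genes was -0.12 for SB/CHIR in static culture, 0.01 for SB/CHIR under shear, 0.00 for shear in DMSO cultures and 0.12 for shear in SB/CHIR cultures. Values below are not shifted by these medians.

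The cultures held blood, endothelial, stromal, skeletal and cardiac cell types side by side, in proportions that differed strongly between conditions. After SB/CHIR, cells resembling blood progenitors were more frequent and cells resembling heart muscle were not found. Under shear, macrophage-like cells took a larger share with either drug treatment. The library that received both treatments held the largest blood share of the 4. The 6 blood classes made up 30.3% of kept cells in static DMSO (28.2 to 32.5), 30.6% in static SB/CHIR (28.4 to 32.9), 20.2% in shear DMSO (18.4 to 22.0) and 50.4% in shear SB/CHIR (48.3 to 52.6). At a clustering resolution of 0.4 these shares were 45.4%, 35.4%, 24.2% and 58.4%, so whether static DMSO held a smaller or larger blood share than static SB/CHIR depends on the clustering. The 6 classes leave out an unnamed cluster with the erythroid marker ALAS2 among its leading genes (258, 50, 77 and 17 cells, same order). They also leave out an unnamed cluster led by genes that include CD74 and HLA-DRA (4, 27, 2 and 154 cells).

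The progenitor-like class, defined by markers of immature blood cells, held 6 of 1742 cells in static DMSO, 89 of 1597 in static SB/CHIR, 3 of 1951 in shear DMSO and 291 of 2152 in shear SB/CHIR. Its share was 5.23 percentage points higher after SB/CHIR in static culture (4.13 to 6.48) and 13.4 points higher under shear (11.96 to 14.9). Between the SB/CHIR libraries it was 7.95 points higher under shear (6.10 to 9.77), and between the DMSO libraries the difference was -0.19 points (-0.61 to 0.16). Cardiomyocyte-like cells made up 7.87% of static DMSO (6.64 to 9.23) and 8.46% of shear DMSO (7.26 to 9.78). None of the 1597 static and none of the 2152 shear SB/CHIR cells fell in that class, with exact upper bounds of 0.231% and 0.171%, and shares of 0.188% and 0.139% at the floor of 3 cells. Chondrocyte or osteoblast-like cells made up 2.12%, 8.83%, 2.26% and 17.1%, in the order static DMSO, static SB/CHIR, shear DMSO, shear SB/CHIR. At the finer clustering resolution of 1.6 the mean SB/CHIR difference of this class was 4.88 points instead of 10.8.

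Macrophage or monocyte-like cells made up 1.26%, 4.70%, 4.05% and 7.99% in the same order. Their share was 3.43 points higher after SB/CHIR in static culture (2.30 to 4.66) and 3.94 points higher under shear (2.498 to 5.40). Under shear it was 2.79 points higher in DMSO (1.77 to 3.85) and 3.30 points higher in SB/CHIR (1.72 to 4.83). Granulocyte-like cells made up 1.95%, 4.01%, 0.666% and 3.86%, but 0.402%, 2.63%, 0.256% and 2.56% at resolution 1.6. Marker counts within the class differed by drug, with the eosinophil gene CLC at 19736, 5388, 27268 and 5173 CPM (counts scaled to a total of 1000000) and the neutrophil elastase gene ELANE at 0, 1032, 0 and 241. Erythroid-like cells made up 1.95%, 5.26%, 0.923% and 3.90%. These shares leave out the unnamed cluster with ALAS2 among its leading genes, which held 14.8%, 3.13%, 3.95% and 0.79%. When each gene was centred within its library before clustering, the direction for erythroid-like cells turned, with 12.8%, 7.58%, 7.95% and 5.62% of cells in that class.

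The direction for stromal-like cells depended on the second treatment, and so did the direction of the shear difference for megakaryocyte-like cells. Stromal-like cells made up 24.7% of static DMSO, 47.2% of static SB/CHIR, 39.4% of shear DMSO and 17.1% of shear SB/CHIR. At resolution 1.6 they made up 23.0%, 24.7%, 38.0% and 7.76%, a static SB/CHIR difference of 1.77 points (-1.12 to 4.67) instead of 22.5. That clustering named a separate smooth muscle or pericyte-like class of 1.09%, 20.04%, 0.564% and 3.76%, whose cells lie mostly in the stromal-like class otherwise. Megakaryocyte-like cells, the precursors of platelets, made up 18.5%, 6.83%, 12.4% and 15.6%. Their SB/CHIR difference under shear, 3.16 points, was 0.146 points at resolution 0.4 (-2.13 to 2.41). Mast, basophil or eosinophil-like cells made up 6.31%, 4.26%, 2.00% and 5.58%. Endothelial-like cells made up 8.50%, 3.07%, 5.59% and 4.00%, lower after SB/CHIR in both formats. The mean SB/CHIR difference of the endothelial-like class was -3.51 points, and at a clustering resolution of 0.4 it was 1.66 points. Unnamed clusters held 26.5%, 10.3%, 24.1% and 11.4% of cells, and the thresholds for naming were chosen after the clusters had been seen.

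**Figure D1:**
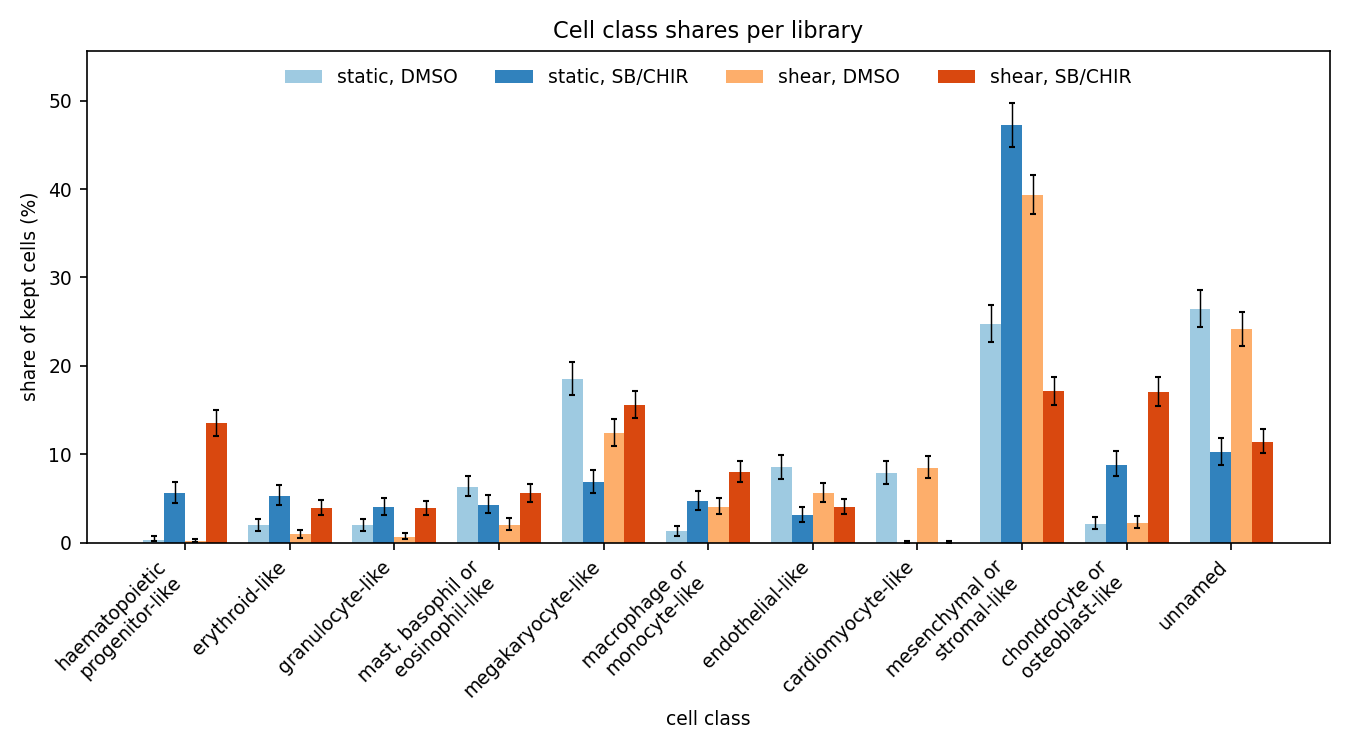
Share of kept cells (percent) in each named class and in unnamed clusters, in the 4 libraries, 1 library per group. Bars start at 0 and lines give exact 95% counting intervals. Progenitor-like cells reach 13.5% in shear SB/CHIR, and cardiomyocyte-like cells are present in the DMSO libraries alone.

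Among the unnamed clusters, 1 with LINC00458, NTS, MSX2 and GATA3 among its leading genes held 98 cells of static DMSO, 175 of shear DMSO and 0 of either SB/CHIR library. Another, led by genes that include CD1C, CD74, HLA-DRA, S100B and LTB, held 4, 27, 2 and 154 cells in the order static DMSO, static SB/CHIR, shear DMSO, shear SB/CHIR. A cluster with GAD1 and ALAS2 among its leading genes held 258, 50, 77 and 17 cells. Cycling cells formed a cluster of 97, 4, 212 and 2 cells and another of 4, 83, 5 and 73 cells. Where a cluster came mostly from 1 library or 1 treatment, a state of the cells and an effect of the library cannot be told apart.

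The SB/CHIR comparison asks what brief inhibition of TGF-beta and activin receptors with activation of WNT signalling, on days 2 to 4, left behind on day 18. HOX genes, which specify position along the body axis, were far higher after SB/CHIR in both culture formats. Genes of the granule proteins of immature granulocytes were higher by more than 10-fold. Genes of the heart muscle sarcomere were lower by larger factors still, and BMP and WNT target genes were lower. Of 11463 genes, 266 were at least 2-fold higher in both formats and 569 at least 2-fold lower, against 43.0 and 125.8 if the directions in the 2 formats were independent across genes.

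All 8 measured genes of the HOXA cluster (chromosome 7, 27092993 to 27200106 on GRCh38) were at least 2-fold higher after SB/CHIR in static culture and under shear. The median log2 ratio was 3.88 in static culture (3.36 to 4.35) and 3.26 under shear (2.73 to 3.75), each at percentile 100 of random lists matched on expression. HOXA9, a factor of definitive blood progenitors, stood at 1.80 CPM in static DMSO, 45.2 in static SB/CHIR, 2.01 in shear DMSO and 30.3 in shear SB/CHIR. HOXA10 stood at 5.40, 72.3, 3.45 and 34.4. All 7 measured HOXC genes were at least 2-fold higher in both formats, with medians of 4.61 (3.84 to 5.33) and 3.77 (2.86 to 4.46). HOXC10 was 35.6-fold higher in static culture (13.4 to 134) and 20.3-fold higher under shear (10.7 to 43.2). The HOXB medians were 1.95 (1.57 to 2.34) and 1.43 (1.06 to 1.62), and the HOXD medians 2.65 (1.78 to 3.37) and 2.33 (1.84 to 3.58). The HOXA medians were 2.61 and 2.65 in sums that give 6 classes their mean share over the libraries. These are the stromal-, megakaryocyte-, chondrocyte-, endothelial-, mast- and macrophage-like classes, and all other cells, among them erythroid-, progenitor- and cardiomyocyte-like and unnamed cells, are left out of such sums.

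Neutrophil granule genes led the ranked genes that were higher after SB/CHIR. PRTN3, a serine protease of neutrophil granules (chromosome 19, 840960 to 848175), was 72.8-fold higher in static culture (40.3 to 147) and 104-fold higher under shear (59.0 to 201). MPO, the myeloperoxidase gene, was 26.4-fold (20.3 to 34.9) and 70.4-fold higher (49.4 to 104). AZU1, which neighbours PRTN3 and encodes azurocidin, was 23.8-fold (14.6 to 41.6) and 61.3-fold higher (32.0 to 135). ELANE, the neutrophil elastase gene, was at least 47.5-fold and at least 21.9-fold higher. SPINK2, found in immature blood progenitors, was at least 38.9-fold higher in static culture and 104-fold higher under shear (40.1 to 383). The defensin gene DEFA4 was 19.7-fold (11.99 to 34.5) and at least 251-fold higher. S100A12, a calcium-binding protein of myeloid cells, was 26.8-fold (13.2 to 63.5) and 14.4-fold higher (9.59 to 22.4). IGJ, the joining chain of antibodies, was 36.1-fold (11.8 to 180) and 214-fold higher (37.8 to 8487). NEFM, a neurofilament gene, was 17.2-fold (11.5 to 26.9) and 12.6-fold higher (10.0 to 15.9).

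The granulocyte marker set had medians of 4.30 in static culture and 4.67 under shear, with 10 of 11 members at least 2-fold higher in each. Class II histocompatibility genes, which present antigen, had medians of 1.83 (1.39 to 2.23) and 3.61 (3.40 to 3.77), with 5 and 8 of 8 members at least 2-fold higher. HLA-DRA stood at 13.3, 72.7, 27.6 and 347 CPM in the order static DMSO, static SB/CHIR, shear DMSO, shear SB/CHIR, and CD74 at 33.3, 164, 45.4 and 572. The macrophage markers had medians of 1.61 and 2.05, and the lymphoid markers 2.10 and 2.97. Embryonic and fetal globins had medians of 1.67 (1.62 to 1.72) and 2.25 (2.18 to 2.31), or 0.81 and 1.25 with per-cell weighting. The list of genes associated with haematopoietic stem cells had medians of 0.74 (0.48 to 1.11) and 0.46 (0.30 to 0.72). Lipid-laden macrophage and lysosome genes had medians of 0.66 (0.50 to 0.84) and 0.60 (0.50 to 0.69), the second of which was -0.02 with 6 classes at their mean share.

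Heart muscle genes were the most reduced group. All 12 measured cardiac genes were at least 2-fold lower in static culture and all 13 under shear, with medians of -6.81 (-7.15 to -6.28) and -7.78 (-8.21 to -7.34). MYL7, an atrial myosin light chain, stood at 2197 CPM in static DMSO and 1922 in shear DMSO, against 0.387 (1 count) in static SB/CHIR and 0 in shear SB/CHIR. It was 5683-fold (1020 to 224483) and at least 3320-fold lower. TNNT2, cardiac troponin T, was 183-fold (119 to 296) and 975-fold lower (513 to 2132). TTN, the titin gene, was 138-fold (92.4 to 215) and 220-fold lower (158 to 316). ACTC1, cardiac actin, was 91.9-fold (67.1 to 129) and 1637-fold lower (560 to 7939). The neighbouring myosin genes MYH6 and MYH7 (chromosome 14) were 587-fold and at least 623-fold lower in static culture, and 1281-fold and at least 1623-fold lower under shear, and their reads are hard to tell apart. NEBL, SMPX, MYL3 and CSRP3 were also among the 10 lowest. GATA4, a transcription factor of the early heart, stood at 43.9, 3.48, 51.0 and 1.35 CPM.

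BMP target genes were lower, with medians of -1.70 (-1.85 to -1.47) in static culture and -2.28 (-2.54 to -2.09) under shear, and 8 and 7 of 10 members at least 2-fold lower. ID3 stood at 344, 148, 395 and 141 CPM in the order static DMSO, static SB/CHIR, shear DMSO, shear SB/CHIR, and MSX2 at 26.1, 2.32, 41.4 and 1.93. WNT target genes had medians of -1.44 (-1.80 to -0.80) and -1.52 (-1.90 to -1.03), with 8 and 7 of 11 at least 2-fold lower. LEF1 stood at 12.6, 3.87, 22.6 and 10.6. The BMP and WNT lists share MSX2 and BAMBI, so their medians are not fully separate results. MSX2 is also among the leading genes of an unnamed cluster found in the DMSO libraries alone. TGF-beta and activin targets had medians of -0.48 (-0.58 to -0.20) and -1.27 (-1.42 to -1.11). Early mesoderm patterning genes had medians of -0.60 (-0.86 to -0.11) and -1.47 (-1.68 to -1.05), but 0.16 and 0.49 with 6 classes at their mean share. Genes responsive to laminar flow had medians of -0.60 (-0.98 to -0.30) and -0.36 (-0.59 to -0.17). The immediate early and dissociation list, a sign of handling, had medians of -0.32 (-0.47 to -0.18) and -0.58 (-0.64 to -0.47).

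The remaining lists had these SB/CHIR medians. Notch targets had a median of 0.05 (-0.22 to 0.20) in static culture and -1.19 (-1.57 to -0.73) under shear, and basement membrane genes -0.33 (-0.59 to -0.21) and -1.73 (-1.81 to -1.62). The contractile list, genes of smooth muscle and pericytes, had medians of 0.10 (-0.04 to 0.23) and -2.39 (-2.72 to -2.13), the second of which was -1.22 with 6 classes at their mean share and -1.56 with per-cell weighting. S phase genes had medians of 0.23 (0.09 to 0.31) and 1.21 (1.17 to 1.37), and G2 and M phase genes 0.01 (-0.10 to 0.14) and 0.60 (0.48 to 0.70). Glycolysis genes had medians of -0.09 (-0.15 to 0.04) and 0.65 (0.55 to 1.05). Genes of the endothelial to haematopoietic transition had medians of -0.25 (-0.36 to -0.05) and 1.38 (1.21 to 1.57), the second of which was -0.18 within endothelial-like cells (-0.76 to 0.45). Interferon response genes had medians of -1.49 (-1.87 to -1.25) and -0.17 (-0.27 to 0.05). Arterial endothelium genes had medians of 0.05 and -0.64, the second of which was 0.17 with 6 classes at their mean share, and venous genes 0.04 and 0.01. Hypoxia response genes had medians of -0.15 and 0.19, cholesterol synthesis genes 0.09 and -0.04, and unfolded protein response genes 0.31 and 0.03. The adult beta-like globin list had fewer than 3 measured members and gave no median.

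**Figure D2:**
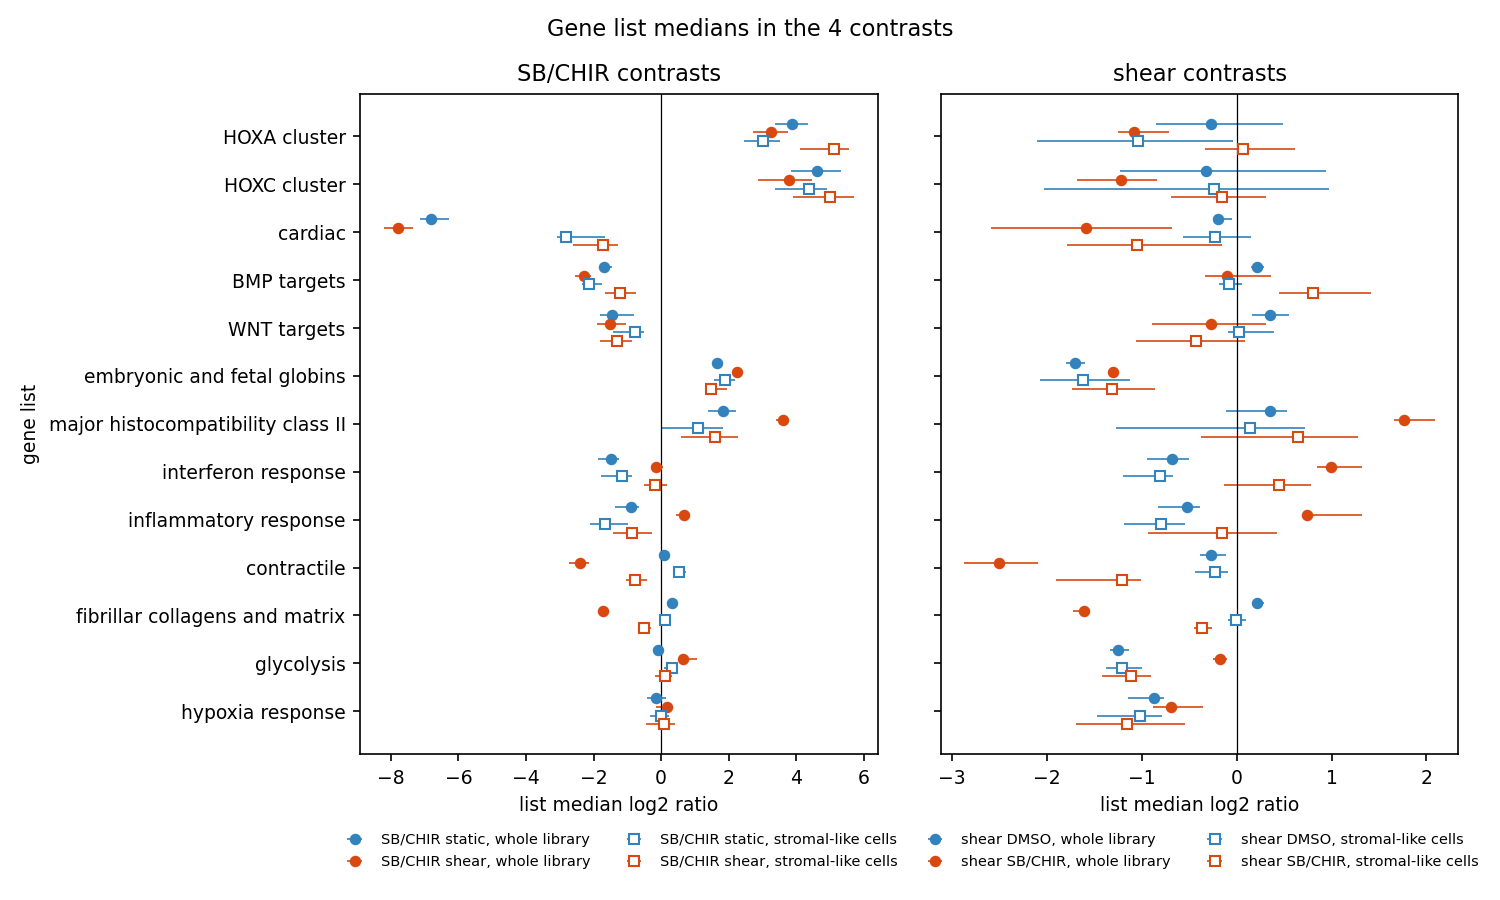
Median log2 ratio (horizontal axis) of selected fixed gene lists in the SB/CHIR contrasts and in the shear contrasts. Circles give whole libraries and open squares stromal-like cells; blue marks the first contrast of a factor (static culture, or DMSO) and orange the second (shear, or SB/CHIR). The HOXA list sits at 3.88 and 3.26 after SB/CHIR, and the cardiac list at -6.81 and -7.78.

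The shear comparison asks what 8 days of orbital movement, a stand-in for flow of the circulation, changed in cultures with the same drug history. Several genes of macrophages, among them complement and lysosomal protease genes, were higher under shear with either drug treatment. Embryonic globins and genes that respond to low oxygen were lower with either drug treatment. Differences shared by both drug treatments were few. Of 11463 genes, 61 were at least 2-fold higher in both drug treatments and 38 at least 2-fold lower, against 12.5 and 21.1 if the directions were independent across genes. Taken singly, 164 were higher and 283 lower in DMSO cultures, and 877 and 855 in SB/CHIR cultures. The incubator was stated as normoxic.

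Genes of macrophages and of matrix breakdown were among those ranked highest. The complement genes C1QB and C1QA were 3.42-fold (2.70 to 4.38) and 3.21-fold higher in DMSO cultures and 4.44-fold (3.75 to 5.30) and 3.25-fold higher in SB/CHIR cultures. MMP9, a gelatinase, was 7.24-fold (3.67 to 16.3) and 4.67-fold higher (3.26 to 6.91), and MMP7, matrilysin, was at least 9.58-fold and at least 33.3-fold higher. CD36, a scavenger receptor, was 3.80-fold (2.92 to 5.02) and 3.77-fold higher (3.07 to 4.65). CTSH, a lysosomal protease, was 6.34-fold (3.58 to 12.2) and 4.86-fold higher (3.55 to 6.82). SIGLEC1, a macrophage lectin, was 6.48-fold and 3.99-fold higher, MS4A6A 4.21-fold and 3.93-fold, and the chemokine gene CCL4, whose close paralogs share sequence, 8.94-fold and 4.44-fold. SPATA22, a meiosis gene, was 6.82-fold (4.40 to 11.1) and at least 7.15-fold higher. The macrophage markers had medians of 0.20 and 1.23, with 8 and 11 of 17 at least 2-fold higher. Lipid-laden macrophage and lysosome genes had medians of 0.57 (0.40 to 0.89) and 0.70 (0.50 to 0.75), and 0.39 and -0.01 with 6 classes at their mean share. SPP1, osteopontin, stood at 96.3, 943, 947 and 1521 CPM in the order static DMSO, static SB/CHIR, shear DMSO, shear SB/CHIR.

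Embryonic and fetal globins were lower under shear in whole libraries. The median was -1.70 in DMSO cultures (-1.80 to -1.60) with 7 of 7 members at least 2-fold lower, and -1.31 in SB/CHIR cultures (-1.33 to -1.28) with 5 of 7. HBZ, the embryonic zeta globin (chromosome 16, 152687 to 154503), was 7.26-fold (6.80 to 7.75) and 4.18-fold lower (4.05 to 4.31). It stood at 1141, 4834, 157 and 1156 CPM in the order static DMSO, static SB/CHIR, shear DMSO, shear SB/CHIR. In static and shear DMSO, 4957 and 1046 HBZ counts lay in 34 and 18 erythroid-like cells, and the intervals leave out variation between those cells. HBM was 5.38-fold and 3.13-fold lower, and HBA1 and HBA2, which are nearly identical, were 3.77-fold and 3.25-fold lower in DMSO and 2.52-fold and 2.32-fold lower in SB/CHIR. The carbonic anhydrase gene CA1, found in red cells, was 10.4-fold and 3.45-fold lower, and MIR451B, a microRNA gene, 8.22-fold and 3.42-fold. The erythroid-like share was 1.03 points lower under shear in DMSO (0.26 to 1.86) and 1.36 points lower in SB/CHIR (0.02 to 2.77). Within erythroid-like cells of the SB/CHIR libraries (84 in each), HBZ was 2.83-fold, HBA1 1.92-fold and HBE1 1.88-fold lower under shear, whereas the ratios of the fetal genes HBG1 and HBG2, whose reads are hard to tell apart, were 1.07 (1.04 to 1.10) and 1.06. With TMM factors the ratios of HBG1 and HBG2 were 0.754 and 0.746, so their direction depends on the scaling. Globin counts within stromal-like cells, which should lack them, had medians of -1.62 and -1.32.

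Genes that respond to low oxygen were lower under shear. Hypoxia response genes had medians of -0.88 in DMSO (-1.15 to -0.76) and -0.70 in SB/CHIR (-0.88 to -0.35), at percentiles 0.00 and 0.06 of random lists. BNIP3, a mitophagy gene induced by low oxygen, was 2.97-fold (2.61 to 3.38) and 4.01-fold lower (3.29 to 4.89). SLC2A1, the glucose transporter GLUT1, was 3.04-fold (2.25 to 4.14) and 2.94-fold lower (2.17 to 4.00). AK4, a mitochondrial adenylate kinase, was 4.14-fold and 5.41-fold lower, and MIR210HG, the host of a microRNA induced by low oxygen, 6.39-fold (3.43 to 12.8) and 15.03-fold (5.30 to 58.7). Glycolysis genes had a median of -1.25 in DMSO (-1.34 to -1.14) with 11 of 16 at least 2-fold lower, and of -0.17 in SB/CHIR (-0.26 to -0.10) with 4 of 16. With 6 classes at their mean share, which leaves out progenitor-like cells, the glycolysis median in SB/CHIR was -0.85, and with per-cell weighting it was -0.38.

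The laminar flow list holds genes that respond to steady flow in endothelium, among them EDN1, CCL2 and TXNIP, and was not fixed by direction. Its median therefore does not separate genes that flow raises from genes that flow lowers. In whole libraries it had medians of 0.07 in DMSO (-0.10 to 0.29) and 0.54 in SB/CHIR (0.10 to 0.77), at percentiles 80.2 and 99.4. KLF4, a factor induced by flow, was 5.51-fold higher in DMSO (2.64 to 13.3) and 2.91-fold higher in SB/CHIR (1.21 to 8.47). THBD, thrombomodulin, was 3.55-fold (2.34 to 5.56) and 2.64-fold higher (1.65 to 4.43). KLF2 was 1.66-fold higher (1.29 to 2.17) and 1.33-fold higher (0.87 to 2.06). HMOX1, haem oxygenase, was 2.94-fold (1.89 to 4.73) and 4.06-fold higher (2.76 to 6.20). These gene ratios pool all cell classes of a library and are not values of endothelial-like cells. HMOX1 was also counted in macrophage or monocyte-like cells, whose share was higher under shear with either drug treatment.

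The remaining lists had these shear medians. In DMSO and then SB/CHIR cultures, the medians were -0.27 and -1.08 for HOXA, 0.15 and -0.31 for HOXB, -0.33 and -1.22 for HOXC and -0.43 and -0.56 for HOXD. They were 0.07 and -0.28 for arterial genes, 0.15 and -0.47 for venous genes, 0.15 and 0.08 for the stem cell associated list and 0.18 and -0.53 for Notch targets. WNT targets had 0.35 and -0.27, TGF-beta and activin targets 0.03 and -0.52, BMP targets 0.21 and -0.10, and the IGF axis 0.03 and -0.44. Niche factors had 0.05 and -0.45, contractile genes -0.27 and -2.51, cardiac genes -0.19 and -1.59 and early mesoderm genes 0.22 and -0.57. S phase genes had -0.09 and 1.03, G2 and M phase genes 0.15 and 0.55, immediate early and dissociation genes 0.14 and -0.05, unfolded protein response genes 0.08 and -0.21, cholesterol synthesis genes -0.09 and -0.29 and class II genes 0.35 and 1.76. With 6 classes at their mean share, venous, niche and early mesoderm genes in SB/CHIR were at 0.39, 0.16 and 0.36 and WNT targets in DMSO at -0.03. Contractile genes in SB/CHIR were at -1.14 in these sums and at -1.79 with per-cell weighting.

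The combination asks whether the SB/CHIR difference under shear departs from that in static culture. Over 11461 genes the median log2 combination value was 0.12, with 1292 genes at 1 or above and 1052 at -1 or below. An additive model with its 1 residual degree of freedom was not fitted, so no difference was tested.

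PAPPA, a protease that frees insulin-like growth factors, had a combination value of -5.12 and stood at 40.1, 95.1, 31.2 and 2.12 CPM in the order static DMSO, static SB/CHIR, shear DMSO, shear SB/CHIR. TNFRSF11B, osteoprotegerin, had -4.75, the endocytic receptor LRP2 -4.21, ACTC1 -4.16 and the cytokine IL33 -4.16. Among positive values, the defensin gene DEFA3 had 7.001 (27.9, 181, 0.287 and 239 CPM), and its reads are hard to tell apart from those of DEFA1. IFI27, an interferon-induced gene, had 5.07 (60.6, 1.55, 9.92 and 8.49). LYZ, lysozyme, had 4.49 (6.75, 11.2, 3.45 and 129). MX1, an antiviral gene, had 4.34 (20.7, 5.80, 7.47 and 42.3). HBD, the delta globin gene, had 4.21 (46.6, 41.8, 20.0 and 332). The named values are the extremes among the genes ranked and have no interval. The low CPM of DEFA3 in shear DMSO and of IFI27 in static SB/CHIR rest on a few counts, so their combination values are imprecise.

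Fibrillar collagen and matrix genes had SB/CHIR medians of 0.33 in static culture (0.23 to 0.40) and -1.71 under shear (-1.86 to -1.61), with 15 of 18 at least 2-fold lower in the latter. Their shear medians were 0.21 in DMSO (0.17 to 0.28) and -1.61 in SB/CHIR (-1.72 to -1.55). COL1A1, a chain of type I collagen, stood at 1549, 2378, 1575 and 337 CPM. ACTA2, smooth muscle actin, stood at 352, 580, 227 and 31.5, and TAGLN, transgelin, at 41.2, 98.6, 32.3 and 5.79. The IGF axis had SB/CHIR medians of 0.55 (0.22 to 0.65) and -0.71 (-0.84 to -0.63), and haematopoietic niche factors 0.43 (0.22 to 0.50) and -0.47 (-0.57 to -0.34). Basement membrane genes had shear medians of 0.39 (0.16 to 0.50) and -1.16 (-1.35 to -0.94). Stromal-like cells made up 47.2% of static SB/CHIR and 17.1% of shear SB/CHIR. At resolution 1.6, the fibrillar shear median in SB/CHIR was 0.07 (-0.02 to 0.18) in stromal-like and -1.13 (-1.31 to -0.93) in smooth muscle or pericyte-like cells. With 6 classes at their mean share the fibrillar medians were -0.09 and -0.48 for SB/CHIR and -0.11 and -0.31 for shear, and 0.16 for the IGF axis and 0.15 for niche factors under shear, -0.07 for niche factors in static culture and -0.02 for basement membrane genes in DMSO.

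Inflammatory, interferon response and transition genes went the other way. Inflammatory genes had SB/CHIR medians of -0.90 in static culture (-1.36 to -0.66) and 0.67 under shear (0.45 to 0.86), and shear medians of -0.53 in DMSO (-0.83 to -0.39) and 0.74 in SB/CHIR (0.70 to 1.32). Interferon response genes had shear medians of -0.68 (-0.94 to -0.51) and 1.00 (0.84 to 1.32). ISG15 stood at 168, 76.9, 68.7 and 141 CPM. Genes of the endothelial to haematopoietic transition had shear medians of -0.90 (-1.07 to -0.70) and 0.61 (0.50 to 0.79). RUNX1, the factor required for that transition (chromosome 21, 34787801 to 36004667), stood at 56.5, 53.0, 28.7 and 101, and MYB, needed in definitive progenitors, at 23.0, 37.1, 5.17 and 150. PF4, a platelet chemokine, stood at 5547, 1613, 2681 and 5926. The inflammatory median for SB/CHIR under shear was -0.31 with 6 classes at their mean share. The transition median for shear in SB/CHIR was -0.09 in these sums, which leave out progenitor-like cells. Whole-library transition medians pool all cell classes. Within endothelial-like cells the transition median was 0.01 for shear in DMSO (-0.28 to 0.52) and -0.18 for SB/CHIR under shear (-0.76 to 0.45). For shear in SB/CHIR, with only 49 static endothelial-like cells, it was -0.23 (-0.84 to 0.81).

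Stromal-like cells came from 4 clusters whose make-up differed by drug and in part by shear. A pair of them held 273 and 114 cells of static DMSO and 362 and 343 of shear DMSO, against 3 and 0 in static and 3 and 0 in shear SB/CHIR. A large one held 502 cells of static and 327 of shear SB/CHIR against 19 and 28 in the DMSO libraries. The last held 25, 249, 35 and 38 cells in the order static DMSO, static SB/CHIR, shear DMSO, shear SB/CHIR. The SB/CHIR contrast within the class is therefore largely between different clusters. Shear contrasts within the class also compare different mixes of these clusters. Of 9386 genes, 196 were at least 2-fold higher and 417 at least 2-fold lower after SB/CHIR in both formats, against 25.1 and 86.0 for independent directions.

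Posterior HOX genes were higher in stromal-like cells after SB/CHIR. The HOXA median was 3.01 in static culture (2.46 to 3.51) and 5.11 under shear (4.11 to 5.55), the first of which was 4.88 at a clustering resolution of 1.6, and the HOXC median 4.36 (3.36 to 4.91) and 4.99 (3.90 to 5.72). HOXA9 was 25.7-fold (8.43 to 128) and 61.3-fold higher (19.5 to 310), HOXA10 15.3-fold (7.80 to 34.2) and 35.3-fold (16.8 to 85.6), and HOXC9 62.7-fold and 33.0-fold. HOXA11 was 24.6-fold and 37.7-fold higher, HOXC10 27.5-fold and 113-fold, the phosphodiesterase gene PDE1A 34.9-fold and 23.4-fold, and the glutamate receptor gene GRIA4 14.6-fold in each. Among genes that were lower, the complement gene C7 was 375-fold and 58.6-fold lower, RGS5, a pericyte marker, 43.4-fold (24.0 to 87.4) and 32.3-fold (16.3 to 74.9), and CGNL1, a junction protein gene, 50.4-fold (28.6 to 98.0) and 44.96-fold (23.6 to 98.5). ASPN was at least 30.6-fold and 66.3-fold lower. The muscle genes SLN and TTN were 96.3-fold and 36.0-fold lower in static culture and 208-fold and 46.9-fold lower under shear, beside cardiac list medians of -2.80 and -1.73 in these cells, and the DMSO libraries are those that held cardiomyocyte-like cells. BMP targets had medians of -2.12 and -1.22. Contractile genes had medians of 0.54 and -0.79, and the static value was -0.22 at a clustering resolution of 1.6, where smooth muscle or pericyte-like cells form a class of their own.

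Summed over 11 HOXA genes, stromal-like cells held 20.2 CPM in static DMSO (13.0 to 29.8), 297 in static SB/CHIR (266 to 331), 9.44 in shear DMSO (6.05 to 14.0) and 313 in shear SB/CHIR (268 to 364). Endothelial-like cells held 3.06, 405, 14.7 and 185. Chondrocyte or osteoblast-like cells were high in every library, at 251, 402, 253 and 317. Progenitor-like cells held 56.6 in static SB/CHIR (30.2 to 96.8) and 71.2 in shear SB/CHIR (55.5 to 90.0), and the 6 and 3 such cells of the DMSO libraries held 0 counts.

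**Figure D3:**
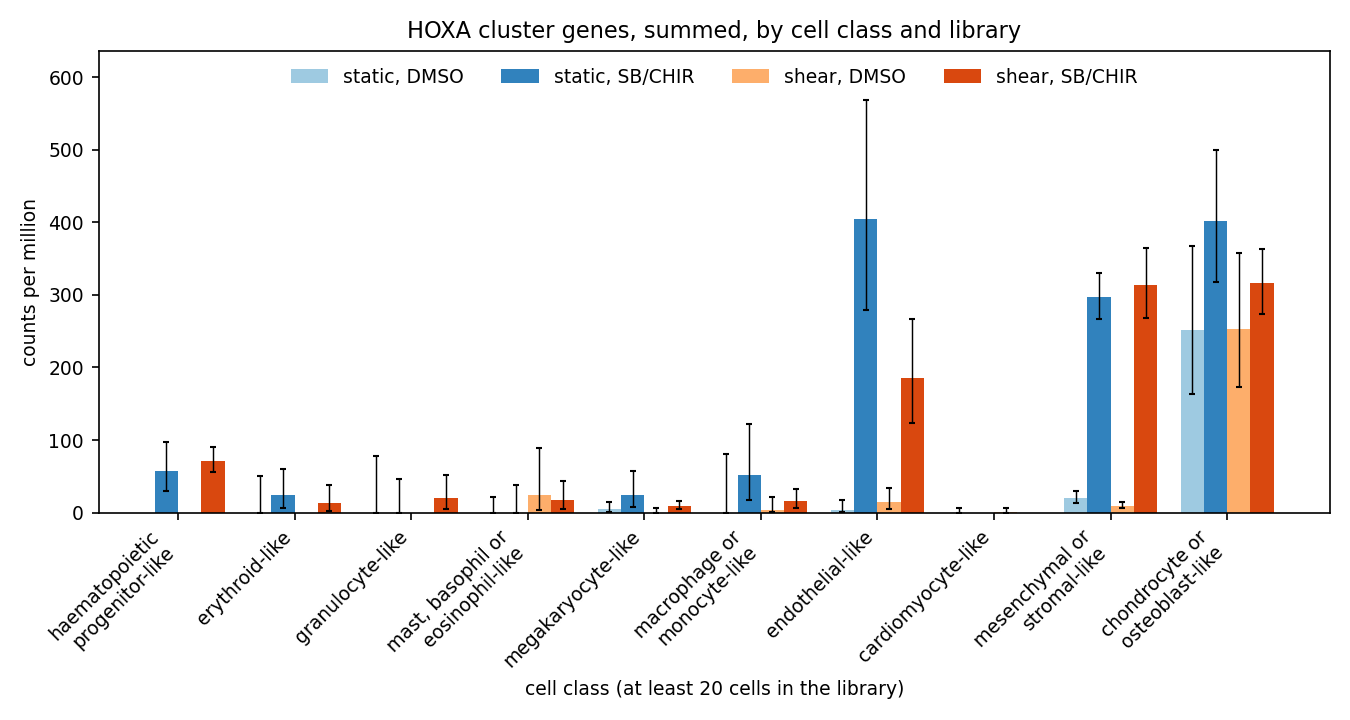
Summed CPM of the HOXA genes (axis starting at 0) in each class with at least 20 cells in a library; bars are the 4 libraries and lines exact 95% counting intervals. Stromal-like cells reach 297 and 313 in the SB/CHIR libraries against 20.2 and 9.44 in the DMSO libraries, while chondrocyte or osteoblast-like cells are above 200 in each.

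In stromal-like cells, fewer genes differed in the same direction in both shear contrasts than in both SB/CHIR contrasts. Of 9386 genes, 48 were at least 2-fold higher and 53 at least 2-fold lower in both drug treatments, against 13.3 and 12.8 for independent directions. Taken singly, 131 were higher and 201 lower under shear in DMSO, and 954 and 599 in SB/CHIR. The single SB/CHIR contrasts had 364 higher and 915 lower in static culture, and 646 and 882 under shear. Glycolysis genes had medians of -1.21 in DMSO (-1.38 to -1.002) and -1.12 in SB/CHIR (-1.42 to -0.91), with 11 and 9 of 16 at least 2-fold lower, and hypoxia response genes -1.02 and -1.16, with 7 of 12 lower in each. ENO1, enolase, was 2.67-fold (2.39 to 2.98) and 2.97-fold lower (2.48 to 3.58), and LDHA, lactate dehydrogenase, 2.98-fold (2.52 to 3.54) and 4.15-fold lower (3.09 to 5.67). GAPDH, whose pseudogenes share sequence, was 3.03-fold and 4.97-fold lower, and SLC2A1 3.80-fold (2.33 to 6.31) and 5.86-fold (2.15 to 22.4). ANKRD1, a target of YAP that responds to mechanical load, was 2.10-fold (1.92 to 2.30) and 29.3-fold lower (20.2 to 44.2). IL32 was 3.85-fold and 6.85-fold lower, and RBM3, a cold-shock RNA-binding protein gene, 2.29-fold and 3.17-fold. Among genes that were higher, MFAP4, a microfibril gene, was 2.31-fold (2.01 to 2.66) and 2.65-fold (2.11 to 3.34), SFRP1, a secreted WNT antagonist, 2.07-fold and 4.37-fold, and the phospholipase gene PLA2G2A 7.15-fold and 5.60-fold. REN, the renin gene, was at least 5.04-fold and 3.99-fold higher, and TFPI2 2.23-fold and 3.06-fold. Contractile genes had medians of -0.23 and -1.21, immediate early genes 0.11 and 1.03, and S phase genes -0.38 and 1.01.

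Glycolysis genes were lower under shear in some other classes. In cardiomyocyte-like cells of the DMSO cultures the median was -1.42, with 11 of 14 at least 2-fold lower, beside -1.35 for hypoxia response genes, -1.68 for interferon genes and -0.10 for cardiac genes. In megakaryocyte-like cells the medians were -0.88 and -0.44, and in endothelial-like cells of DMSO cultures -0.90. In macrophage or monocyte-like cells of SB/CHIR cultures the median was -0.75. In progenitor-like cells of SB/CHIR cultures it was 0.16. In erythroid-like cells of those cultures (84 in each library) 9 genes gave 0.56, at percentile 47.9 of random lists, or 0.05 with TMM factors, with ENO1 2.40-fold higher (1.69 to 3.47). Again in SB/CHIR cultures, mast-like, granulocyte-like and chondrocyte-like cells had -0.07, -0.13 and -0.24. Summed over the list, progenitor-like cells held 4264 CPM in static and 4001 in shear SB/CHIR, and stromal-like cells 2814 and 1107.

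**Figure D4:**
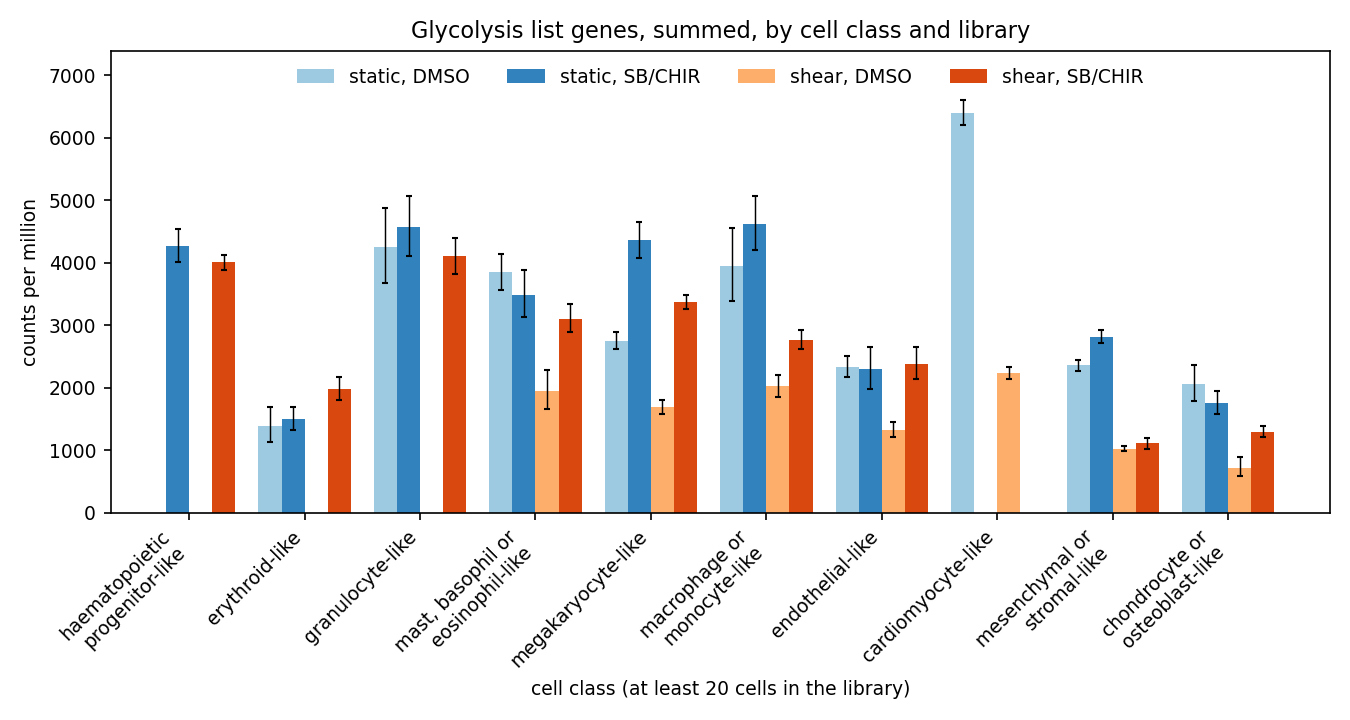
Summed CPM of the glycolysis genes (axis starting at 0) in each class with at least 20 cells in a library; bars are the 4 libraries and lines exact 95% counting intervals. Stromal-like cells stand at 2355 in static and 1019 in shear DMSO, and progenitor-like cells at 4264 in static and 4001 in shear SB/CHIR.

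Megakaryocyte-like cells differed more by drug than by shear, and they came from 3 clusters whose shares differed between libraries. Of 5710 genes, 385 were at least 2-fold higher and 206 at least 2-fold lower after SB/CHIR, against 142.3 and 65.3 for independent directions, and 42 and 37 under shear against 24.3 and 19.3. These counts depend on the scaling, and with TMM factors they were 235 and 342 after SB/CHIR and 64 and 22 under shear. S phase genes had SB/CHIR medians of 1.06 in static culture and 2.87 under shear. HBD was 5.51-fold and 7.25-fold higher after SB/CHIR, and GYPB, a red cell surface protein whose reads overlap with GYPA, 14.0-fold and 11.6-fold. CPT1A, which admits fatty acids to mitochondria, was 22.5-fold and 27.3-fold higher, ACAA2, of fatty acid oxidation, 14.0-fold and 7.38-fold, and CDKN1C 7.15-fold and 6.95-fold. CD74 was 30.9-fold and 19.5-fold higher, HCK 10.7-fold and 15.2-fold and S100A4 4.31-fold and 5.61-fold. KDR, a receptor for vascular endothelial growth factor, was 7.12-fold and 5.87-fold lower, KLF10, induced by TGF-beta, 7.35-fold and 7.32-fold, and the kinase gene DGKI 7.21-fold and 7.86-fold. Under shear, HES1, a Notch target, was 4.29-fold and 4.51-fold lower, BNIP3 4.87-fold and 4.74-fold lower, CPA3, a mast cell protease, 8.55-fold and 6.84-fold higher and GUCY1A3 3.33-fold and 3.65-fold higher. HBD was 2.15-fold and 2.83-fold higher under shear. At other clustering resolutions the DMSO log2 ratio was -0.13 instead of 1.11 for HBD and 0.01 instead of -2.10 for HES1.

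Endothelial-like cells came from 2 clusters whose mix differed between libraries. The one with EDN1, APLNR and TEK among its leading genes held 121, 3, 71 and 0 cells in the order static DMSO, static SB/CHIR, shear DMSO, shear SB/CHIR. The other, with CLDN5, GJA5, CDH5 and CD34, held 27, 46, 38 and 86. CD34 stood at 76.6, 662, 334 and 1202 CPM in these cells. Genes responsive to laminar flow had a shear median of 0.45 in DMSO at percentile 99.7. THBD was 10.9-fold (5.30 to 26.0) and KLF2 2.32-fold higher (1.42 to 3.90) under shear in DMSO. With SB/CHIR under shear, HOXB genes had a median of 2.22, G2 and M phase genes 3.00 with 8 of 8 members at least 2-fold higher, fibrillar genes -2.38 and BMP targets -1.47. LYVE1, a marker of lymphatic and yolk sac endothelium, stood at 18.4, 159, 70.4 and 1268. SOX17, at 2, 4, 16 and 10 counts, was too rarely counted for a comparison.

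Macrophage or monocyte-like cells could be compared between the SB/CHIR libraries (172 cells under shear and 75 in static culture). Under shear, inflammatory genes had a median of 1.28, interferon response genes 1.02 and cholesterol synthesis genes 0.94. All 5 measured hypoxia response genes were at least 2-fold lower, with a median of -1.23, and immediate early genes had a median of -1.01. HLA-DRA stood at 626 CPM in static and 1217 in shear SB/CHIR, HMOX1 at 136 and 375, and FOS at 313 and 104. Progenitor-like cells could be compared between the same libraries (291 and 89 cells). MYB stood at 442 CPM under shear and 183 in static culture, MKI67, of dividing cells, at 737 and 396, and PCNA, of DNA replication, at 337 and 196. S phase genes had a median of 0.52, and fetal and embryonic globins -1.41. Haemoglobin genes took 3.33% of all counts in static and 1.99% in shear SB/CHIR. Globin counts were also lower in stromal-like cells, which should lack them. The globin value of progenitor-like cells therefore cannot be told apart from a difference in free globin RNA between the libraries. SPINK2 stood at 278 and 257, CD34 at 177 and 205 and HOXA9 at 47.8 and 34.8. Median counts per progenitor-like cell were 2739 under shear and 1548 in static culture.

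The reporter line carries a fluorescent protein at RUNX1C, and the count tables list a feature named mEGFP. Of kept cells, 1.26% had a count in static DMSO (0.79 to 1.91), 1.94% in static SB/CHIR (1.32 to 2.74), 0.615% in shear DMSO (0.32 to 1.07) and 4.32% in shear SB/CHIR (3.50 to 5.27). Of its 234 counts, 115 lay in megakaryocyte-like cells, 70 in mast, basophil or eosinophil-like cells, 21 in progenitor-like and 10 in granulocyte-like cells. Among mast, basophil or eosinophil-like cells 6.36%, 23.5%, 10.3% and 14.2% had a count, in the order static DMSO, static SB/CHIR, shear DMSO, shear SB/CHIR, at median depths of 1284, 1083.5, 1620 and 1553 counts. Among stromal-like cells, which should lack it, 0.232%, 0.265%, 0.130% and 0% had a count, at median depths of 2468, 1138, 2810 and 1200.5. That the feature is the transcript of the RUNX1C reporter is not stated.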

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

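The test with finer cell classes was chosen after the results were seen, and the other tests of this part were set down before. Shares and gene lists appear here because a contrast went one way in 1 pair of libraries and the opposite way in the other pair, beyond counting error and, for gene lists, outside the middle 95% of random lists. Contractile genes do not meet that rule and are weighed beside the matrix genes, and mEGFP appears because its counts lie outside the comparisons. With 1 library per group the differences between pairs were not tested.

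Fibrillar collagen and matrix genes had SB/CHIR medians of 0.33 in static culture and -1.71 under shear, a difference of -2.03, and shear medians of 0.21 in DMSO and -1.61 in SB/CHIR, a difference of -1.82. Different shares of cell classes are a candidate explanation for most of it, since the shear median in SB/CHIR was -0.31 with 6 classes at their mean share (-0.42 to -0.22), although at resolution 1.6 it was -1.13 within smooth muscle or pericyte-like cells (-1.31 to -0.93). For contractile genes, class shares alone are argued against, as the median was -1.14 with 6 classes at their mean share (-1.72 to -0.94), and -1.11 (-1.61 to -0.76) with the classes of resolution 1.6, where smooth muscle or pericyte-like cells made up 20.04% of static and 3.76% of shear SB/CHIR and had a median of -1.15 (-1.68 to -0.93). A shift between stromal clusters stays open for both lists, because contractile genes within the largest cluster of that drug, -0.63 (-1.13 to -0.24), lie between no change and the whole change, and matrix genes there, -0.28 (-0.46 to -0.17), hardly differ from the whole stromal-like class, -0.37 (-0.45 to -0.26). An effect of the combined treatment and an effect of that 1 library both stay open.

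The other opposed results are given as values, and their differences were not tested. The stromal-like share was 22.5 points higher after SB/CHIR in static culture and changed by -22.3 points under shear, a combination of -44.7 points. At resolution 1.6, with smooth muscle or pericyte-like cells as a class of their own, the static difference was 1.77 points (-1.12 to 4.67). The same combination of -44.7 points separates the shear differences of 14.6 points in DMSO and -30.1 points in SB/CHIR. The megakaryocyte-like share changed by -11.7 points after SB/CHIR in static culture and by 3.16 points under shear, a combination of 14.8 points. The second value was 0.146 points at resolution 0.4 (-2.13 to 2.41) and -1.45 points with genes centred within libraries (-3.17 to 0.24), so the opposed drug directions depend on the clustering. Its shear differences were -6.08 points in DMSO and 8.74 points in SB/CHIR. The mast, basophil or eosinophil-like share changed by -2.06 points after SB/CHIR in static culture and by 3.58 points under shear, a combination of 5.63 points, or 2.68 points with the strict cell filter.

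Among gene lists, the IGF axis had SB/CHIR medians of 0.55 in static culture and -0.71 under shear, a difference of -1.26. Haematopoietic niche factors had 0.43 and -0.47, a difference of -0.89. Inflammatory response genes had -0.90 and 0.67, a difference of 1.57, and shear medians of -0.53 in DMSO and 0.74 in SB/CHIR, a difference of 1.27. Basement membrane genes had shear medians of 0.39 and -1.16, a difference of -1.55. Interferon response genes had shear medians of -0.68 and 1.00, a difference of 1.68. Genes of the endothelial to haematopoietic transition had -0.90 and 0.61, a difference of 1.503. With 6 classes at their mean share some of these turned: the IGF axis to 0.16 and niche factors to 0.15 for SB/CHIR under shear, niche factors to -0.071 in static culture, inflammatory genes to -0.31 for SB/CHIR under shear, and basement membrane genes to -0.016 for shear in DMSO. The transition list turned to -0.089 for shear in SB/CHIR in these sums, which leave out progenitor-like cells. Within endothelial-like cells the transition list had shear medians of 0.01 in DMSO (-0.28 to 0.52) and -0.23 in SB/CHIR (-0.84 to 0.81). The second value rests on only 49 static cells.

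A feature named mEGFP, which is no human gene and lies outside the comparisons, had 234 counts over the 4 libraries. Of these, 49.1% lay in megakaryocyte-like cells and 29.9% in mast, basophil or eosinophil-like cells.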

How the results depend on the processing

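Thinning to the smallest library, a class minimum of 40 cells and standardising with the classes of resolution 1.6 were chosen after seeing the data; other alternatives were fixed before. No paired analysis was possible because each group is 1 library with no pairing stated. Of 655 list medians recomputed, 480 moved by less than their counting interval, 152 by more and 23 turned. Of 180 class share differences the numbers were 143, 35 and 2, and of 1118 named gene ratios 1015, 99 and 4. Of 72 counts of genes, 51 stayed within 1.5 times. Depth limits rare features such as SOX17. Except where a size threshold or filter sets a count by construction, the cause was not tested for any value below.

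Genes higher and lower after SB/CHIR (266 and 569) and under shear (61 and 38) numbered 539, 884, 133 and 171 with a filter of 20 counts, and 86, 240, 19 and 11 with 500. They numbered 591, 1113, 211 and 173 at 1.5-fold, and 118, 297, 14 and 8 at 3-fold. In megakaryocyte-like cells, the 385 genes higher after SB/CHIR numbered 248 at resolution 0.4 and 235 with TMM factors. With TMM factors, the 206 lower numbered 342, and 42 higher and 37 lower under shear numbered 64 and 22.

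Class shares are in points, as the mean difference of a factor or as the combination. For SB/CHIR, cardiomyocyte-like -8.16 was -5.95 at resolution 0.4, -5.73 at 1.6 and -7.13 with genes centred within libraries. Endothelial-like -3.51 was 1.66 at 0.4 and -2.42 centred, and its combination 3.84 was 0.667 at 0.4. Erythroid-like 3.14 was 2.28 with the strict cell filter and -3.77 centred, and its shear difference -1.19 was -3.41 centred. Chondrocyte or osteoblast-like values at 1.6 were 4.88 for SB/CHIR, 1.84 for shear and 3.60 for the combination. Progenitor-like 9.30 was 14.0 at 0.4 and 11.6 centred. Its shear difference 3.88 was 2.56 strict, 6.82 at 0.4 and 4.89 centred, and its combination 8.14 was 14.5 and 11.5 at 0.4 and centred. The mast-like combination 5.63 was 2.68 strict. Megakaryocyte-like -4.25 was -1.92 with every barcode, -2.53 strict, -11.7 at 0.4, -8.77 centred and -6.04 without called doublets, and its combination 14.8 was 23.6 at 0.4. Stromal-like shear -7.75 was -0.952 at 1.6, and the combination -44.7 was -32.0. The share of the 6 blood classes moved by more than its interval in 15 of 24 recomputations, and that of static DMSO, 30.3%, lay between 25.7% at 1.6 and 45.4% at 0.4.

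List medians follow, in whole libraries. With TMM factors globins were at 1.75 for SB/CHIR in static culture and -1.36 for shear in SB/CHIR. With per-cell weighting, fibrillar genes were at -1.18 for SB/CHIR under shear and -1.04 for shear in SB/CHIR, contractile genes at -1.56 and -1.79, and cardiac genes at -5.80 and -6.60 for SB/CHIR in static culture and under shear. Globins were then at 0.81 and 1.25 for SB/CHIR and -1.25 and -1.07 for shear. For shear in SB/CHIR, glycolysis was at -0.38 and lipid-laden macrophage genes at 0.42. With a member minimum of 100 counts, cardiac genes under shear were at -8.25.

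Giving 6 classes their mean share leaves out erythroid-, granulocyte-, progenitor- and cardiomyocyte-like and unnamed cells, so globin, cardiac, class II and transition values there come from other cells. These turned for SB/CHIR under shear: arterial 0.17, IGF axis 0.16, niche factors 0.15, early mesoderm 0.49, inflammatory -0.31 and lipid-laden -0.019. For SB/CHIR in static culture, niche factors turned to -0.071, fibrillar to -0.093, early mesoderm to 0.163 and class II to -0.071. For shear in SB/CHIR, venous turned to 0.39, endothelial to haematopoietic transition to -0.089, niche factors to 0.16, early mesoderm to 0.36 and lipid-laden to -0.012. For shear in DMSO, WNT targets turned to -0.027, fibrillar to -0.107 and basement membrane to -0.016. Without turning, HOXA was at 2.61 and 2.65, cardiac at -3.23 and -4.05 and globins at 0.78 and 0.47 for SB/CHIR. Fibrillar was at -0.48 and contractile at -1.22 for SB/CHIR under shear, and -0.31 and -1.14 for shear in SB/CHIR, where the classes of resolution 1.6 gave -0.41 and -1.11. For shear in DMSO and SB/CHIR, globins were at -0.09 and -0.42 and hypoxia at -1.23 and -1.01. Glycolysis was at -0.85 for shear in SB/CHIR, and lipid-laden at 0.39 for shear in DMSO.

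Within stromal-like cells at resolution 1.6, HOXA was at 4.88 for SB/CHIR in static culture, and fibrillar turned to 0.07 for SB/CHIR under shear and for shear in SB/CHIR (0.066 and 0.072). Contractile turned to -0.22 for SB/CHIR in static culture. Within megakaryocyte-like cells under shear in DMSO, HBD turned to -0.13 at 0.4, and at 1.6 HES1 turned to 0.01 and fibrillar to -0.61. Within erythroid-like cells under shear in SB/CHIR, TMM factors turned HBG1 to -0.41 and HBG2 to -0.42. Without called doublets, megakaryocyte-like fibrillar turned to 0.28 for SB/CHIR in static culture.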

Other observations

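Tests here that were chosen only after the result was seen are those of class shares, of a library effect and of a weaker hypoxia response for glycolysis genes, and of free RNA for HOXA counts in progenitor-like cells, besides the class minimum of 40 cells. The patterns were found and tested on the same data and are hypotheses.

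With the minimum lowered to 40 cells, endothelial-like cells of the SB/CHIR cultures could be compared between shear (86 cells) and static culture (49 cells). Genes that respond to laminar flow had a median of 1.52 (0.28 to 2.01) over 15 members, at percentile 100 of random lists. Of these, 8 were at least 2-fold higher and 2 at least 2-fold lower. G2 and M phase genes had a median of 3.11 (2.12 to 3.52), with 8 of 8 at least 2-fold higher. S phase genes had 1.22 (0.69 to 1.79), and class II genes 2.33 (1.33 to 3.50) over only 3 members. THBD, thrombomodulin, had 84 counts under shear and 0 in static culture, and KLF2, a factor induced by flow, had 31 and 2. Arterial genes had a median of -0.84 and venous genes 0.76, and glycolysis genes -0.03. Genes of the endothelial to haematopoietic transition had -0.23 (-0.84 to 0.81) over 6 members, at percentile 24.9. Of these cells, 86 under shear and 46 in static culture came from the cluster with CLDN5 and GJA5 among its leading genes.

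In static culture the same class gave an SB/CHIR comparison (49 against 148 cells) in which HOXB genes had a median of 2.47, arterial genes 1.16, stem cell associated genes 0.75 and the IGF axis 0.69. Fibrillar genes had -1.50, interferon genes -1.26 and immediate early genes -1.34. Genes of the endothelial to haematopoietic transition had 0.25 (-0.43 to 0.88). The DMSO cells came mostly from the cluster with EDN1 and APLNR, so the clusters differ between these libraries.

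Glycolysis genes were lower under shear, with whole-library medians of -1.25 in DMSO and -0.17 in SB/CHIR. Different shares of the named classes are argued against, since the medians within stromal-like cells were -1.21 and -1.12, and so is depth per cell, since stromal-like cells of 1000 to 2000 counts gave -1.15 in DMSO and -1.19 in SB/CHIR. A shift between clusters within the stromal-like class was not tested and stays open. In SB/CHIR, its clusters went from 249 cells in static culture to 38 under shear and from 502 to 327. In DMSO, another went from 114 to 343. An effect of the library on these transcripts in every class alike is argued against by progenitor-like cells, whose median was 0.16 (-0.21 to 0.30) where the same 13 members gave -1.13 in stromal-like cells (-1.39 to -0.87). A weaker hypoxia response under shear is a candidate explanation. In stromal-like cells the 9 hypoxia genes outside the glycolysis list had medians of -0.98 and -0.95, at percentiles 0.00 and 0.02. The whole hypoxia list was already known to be lower in these cells, so this test could hardly have failed and does not decide the question. Lower values in both lists do not show that one explains the other. In DMSO and then SB/CHIR the whole hypoxia list had medians of -0.94 (-1.21 to -0.11) and -0.135 (-0.83 to 0.02) in megakaryocyte-like cells. In endothelial-like cells it had -1.02 (-1.50 to -0.44) and 0.36 (-0.63 to 1.15). Effects of dissociation or of a sequencing pool that differ between classes stay open, because the libraries share name endings within static and within shear culture.

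HOXA genes were higher after SB/CHIR, and different class shares as the whole cause are argued against by medians of 2.61 in static culture (2.03 to 3.22) and 2.65 under shear (1.98 to 3.28) with 6 classes at their mean share. Whether cells of 1 type changed stays open, because the stromal-like class consists of different clusters per drug, the largest with 502 and 327 cells of the SB/CHIR libraries against 19 and 28 of the DMSO libraries. In progenitor-like cells of the SB/CHIR libraries, free RNA from stromal cells is argued against as the whole source, since 83 counts in 380 cells gave a level 5.30 times that of 4 other blood classes (3.45 to 8.34), where 947 cells held 30 counts. These were the erythroid-, granulocyte-, mast- and megakaryocyte-like classes, and macrophage or monocyte-like cells were left out of the comparison. Whether progenitor-like cells of DMSO cultures differ stays open, as the DMSO libraries held 6 and 3 of them. An effect of the drug and an effect of single libraries cannot be separated with 1 library per group, although both SB/CHIR libraries went the same way.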
